A study of Actinobacillus pleuropneumoniae with 15 samples.

How the data were processed

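Total RNA of 15 strains of Actinobacillus pleuropneumoniae, the bacterium of porcine pleuropneumonia, was measured on 1-colour Agilent arrays with 1 array per strain. Per the labels' protocols, the strains grew at 37 °C in tryptic soy broth with NAD and cattle serum and were collected in mid-log phase. RNA was extracted with Trizol, transcribed into cRNA and labelled with Cy3. The labels name a serotype and a strain for each array. They give 14 serotype or subtype labels, of which serotype 3 alone is carried by 2 strains, and the subtypes 5a and 5b belong to 1 serotype number. Nothing in the labels says that a strain was cultured more than once.

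The deposited scanner files hold spot intensities on a linear scale, made with Agilent Feature Extraction. The submitters' processing notes give version 9.5 of that program and the file headers give version 10.5.1.1. Per the file headers, the processed intensity of a spot is background-subtracted and spatially detrended by the scanner software, and it is not normalized between arrays. Each array carried 14866 spots, of which 536 were control spots and were left out. The other 14330 spots held 2866 probes with 5 spots each, and every probe had its own gene identifier. The identifiers carry the prefixes APJL, NC, APP_1 and APP_5. The files used here do not pair the identifiers with gene names or products. For this reason the 22 gene lists fixed before the data were examined, and the levels of the Apx toxin genes, could not be evaluated, and at most 2 identifiers in each direction are printed per comparison. A genome or annotation was not used here.

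The deposited value table holds log2 values, and per the labels' design text the authors normalized the intensities and took logarithms. The highest value was 19.4 in each of its 15 columns and the column medians lay between 14.6 and 14.9, as a quantile normalization leaves them, with dim probes left empty. The method and the filter are not given in the sources used here. The values are levels and no centring was seen. When each column was set against the scanner arrays, 12 of the 15 columns correlated best with the array of another sample than the one they are labelled with. The table was therefore used with its columns as labelled and only as an alternative to the scanner values, and no column was reassigned.

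Spots marked as outliers by the scanner software were dropped (199 to 1689 of the 14330 spots per array), and 11 probes with every spot so marked on an array were kept on all spots. No spot was saturated. The log2 of the processed intensity was averaged over the spots of a probe, and the 75th percentile of each array was subtracted. A probe was called detected on an array when more than 50% of its spots were well above background by the scanner software's own test. The 2757 genes detected on at least 2 arrays were tested. The percentile scaling assumes that the upper part of the signal distribution is alike in all strains, which moves the balance of higher and lower genes when it is not. A probe gives little signal in a strain that lacks the gene or carries a diverged sequence, so a low value can reflect the probe as well as the level of the transcript. Detected shares lay between 84.6% and 90.6% of probes, and the median signal was 890 to 2902 times that of the negative control spots. The median standard deviation between spots of a detected probe was 0.055 to 0.077 on the log2 scale. This is technical precision within an array, and the number of arrays limits the precision of every comparison.

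Genes were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The comparisons tested were serotype 3 against the other serotypes, serotype 5 against the other serotypes, and serotype 3 against serotype 5 in a model with a term for the remaining strains. The spread in these tests is that between strains, each measured once, and it contains culture, labelling and array effects. For a gene below background on most arrays, it can be largely the scatter of values below background. A gene below background on all arrays of a set has only a bound there. The bound is the difference between the mean of the bright set and the mean, over the dim set, of the higher of each array's lowest detected signal and the dim probe's own value. The 4 identifier prefixes were tested as gene sets with camera, at its preset correlation of 0.01 and at an estimated correlation. The comparisons of single strains have no test and use a log2 difference of 1, the size the design text names, with the error from the 5 spots. Fits within a slide, or with an array left out, that leave 1 array on a side take their spread from the other strains and assume that the single array varies like them.

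The rule for named genes took the genes with the largest differences past the threshold, or the smallest p-values where fewer than 5 genes passed. Only genes detected on at least 1 array of each side were ranked by difference, and genes below background on all arrays of a side were ranked apart by their bound. For JL03 against S1421 only genes detected on both arrays were ranked. This separation was not written in the rule and was made after the data had been seen. The alternatives were normexp background correction with an offset of 50, quantile normalization, scaling to the median, the deposited value table, no filter or a filter to probes detected on all 15 arrays, the slide as a block, an intensity trend with robust moderation, 1 model term per serotype, and each array left out in turn. These choices and the models were fixed before the data were examined. The mean spot signal is not in the scanner files used here, so normexp was run on the median spot and background signals instead. Fits within each slide, and fits without the arrays labelled K17 and 4074, were added after the data had been seen. The arrays lay on 2 slides that were scanned separately, 8 on slide 1 and 7 on slide 2, and both the serotype 3 pair and the serotype 5 pair were divided between the slides. Each fitting step was tested on simulated data with 50 genes changed per size among 2757. The simulated noise was normal, with each gene's own spread, and independent between genes and arrays. Real genes and arrays vary together, so the false calls are not the error rate of these data. The simulation was drawn 20 times. For serotype 3 against the other serotypes, the median share recovered was 10% for log2 differences of 1 (2% to 22% over the draws), 42% for 2 (32% to 56%), 68% for 4 (60% to 80%) and 81% for 6 (70% to 96%), with 1 to 9 false calls. For serotype 5 against the other serotypes the medians were 12% (6% to 24%), 45% (30% to 60%), 72% (56% to 84%) and 80% (70% to 92%), with 2 to 9 false calls. For serotype 3 against serotype 5 they were 4% (0% to 14%), 30% (18% to 42%), 62% (54% to 82%) and 75% (66% to 90%), with 2 to 9 false calls. Figures were drawn with matplotlib 3.10.9.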

Results

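Transcript levels were measured in 15 strains of Actinobacillus pleuropneumoniae grown to mid-log phase, 14 of them the reference strains of serotypes 1 to 13 (with subtypes 5a and 5b) and 1 the serotype 3 field strain JL03. Each strain was measured on 1 array, so no strain has a replicate. The median signal per array ranged from 10425 to 32886 intensity units. The arrays lay on 2 slides. With the slide as the only term, 161 of 2757 genes differed between the slides in limma's test with Benjamini-Hochberg adjustment, 89 of them higher and 72 lower on slide 2. Each strain lay on only 1 slide, so differences between the slides cannot be told apart from differences between their strains.

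Most probes gave signal in every strain, and the rest divided the strains. Of the 2866 probes, 2188 (76.3%) were well above background on all 15 arrays, 625 on some but not all, and 53 on none. The share detected on all arrays was 87.7% of the 2089 probes with the prefix APJL, 56.8% of the 419 with the prefix NC, 34.2% of the 228 with the prefix APP_1 and 30.0% of the 130 with the prefix APP_5. The JL03 array detected 99.9% of the APJL probes and the array of the serotype 3 reference strain S1421 detected 99.5%, against at most 97.7% on any other array. All 130 APP_5 probes were detected on the array of the serotype 5b strain L20, whereas the array labelled K17, the serotype 5a strain, detected 44.6% of them and no other array more than 56.9%. The serotype 7 strain WF83 and the serotype 8 strain 405 detected 94.3% and 94.7% of the NC probes, and the highest share elsewhere was 79.7%, in the serotype 6 strain Femφ. For the APP_1 probes the highest share was 66.7%, on the L20 array, and the array labelled 4074 detected 52.2%. A group of 30 probes, 27 of them with the prefix NC, was detected on the serotype 7 and 8 arrays and on no other. The L20 array alone detected 49 probes, of which 30 were APP_5 and 18 APP_1 probes.

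**Figure D1:**
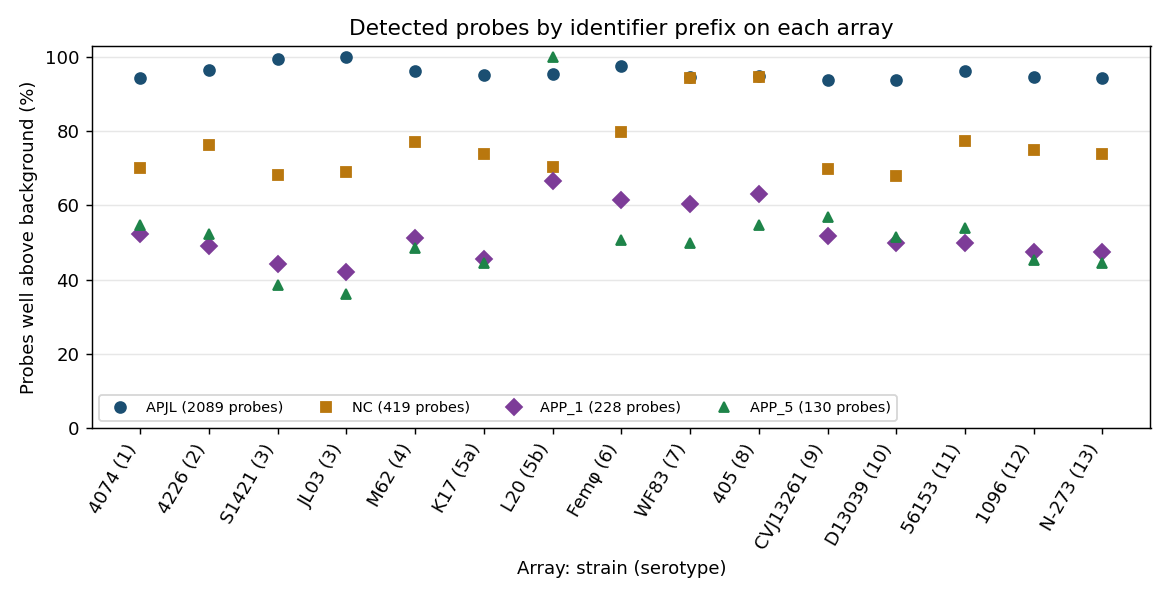
Share of probes well above background (vertical axis, percent) on each of the 15 arrays (horizontal axis, strain with serotype in parentheses), with 1 symbol per identifier prefix. The JL03 array reaches 99.9% of APJL probes, the L20 array 100% of APP_5 probes, and the WF83 and 405 arrays 94.3% and 94.7% of NC probes.

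The first comparison asked how far the transcript levels of single strains depart from the rest, at the log2 difference of 1 that the design text uses. A strain differed from the median of the other 14 at 756 of the 2757 genes in the median, from 533 genes in the serotype 2 strain 4226 to 1071 genes in the serotype 8 strain 405. Strain 405 had 397 genes higher and 674 lower, and the serotype 10 strain D13039 had 451 higher and 555 lower. The counts of 405 can depend on the percentile scaling. Its array had a 75th percentile of 100681 and a median of 15289 intensity units, against medians over all arrays of 74554 and 18520. Its middle genes therefore stood lower after scaling than on a typical array, and counts under median scaling were not compared by strain. The serotype 3 strain S1421 had the most genes higher, 489, and the serotype 6 strain Femφ had 411 higher and 260 lower. With 1 array per strain no test of these counts was possible. The error of a gene's value from its spots was small beside the threshold, with a median standard error per array of 0.026 to 0.037 log2 units, but it leaves out the variation between cultures. Among the 2188 genes detected on all arrays the median count was 465, and at a log2 difference of 2 over all genes it was 327.

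Levels varied across strains by a median standard deviation of 0.87 log2 units over the 2757 genes and of 0.71 over those detected on all arrays. APJL_1880 had the widest spread of the genes detected throughout, with a standard deviation of 5.19 and levels from −10.30 in the serotype 9 strain CVJ13261 to 3.16 in the serotype 13 strain N-273. APJL_1581 had the narrowest, with a standard deviation of 0.14 and a 1.46-fold range over the 15 strains.

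**Figure D2:**
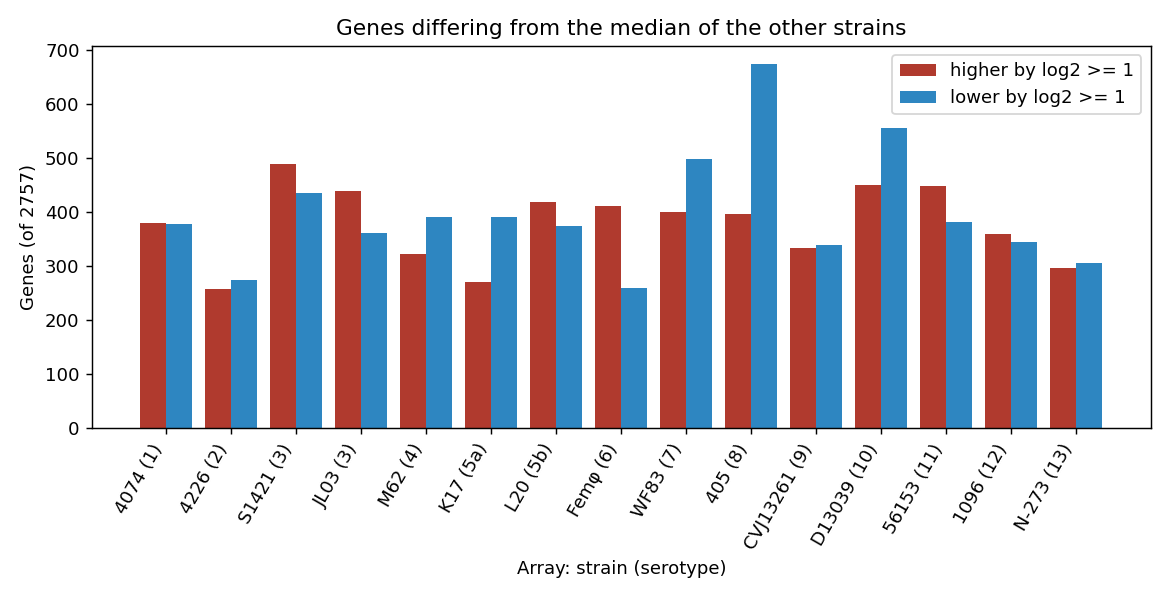
Number of genes (vertical axis, of 2757) whose log2 value on an array lies at least 1 above (red) or below (blue) the median of the other 14 strains, for each array (horizontal axis, strain with serotype in parentheses). Strain 405 has the most genes in total, 1071, and strain 4226 the fewest, 533.

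The second comparison asked whether strains that share a serotype are more alike than strains that do not. The serotype 3 strains S1421 and JL03 were close, with a Pearson correlation across genes of 0.938, the 9th highest among all pairs of arrays. The subtypes 5a and 5b were not, with a correlation of 0.707 between the array labelled K17 and L20, rank 59, against a median of 0.716 over all pairs. By Spearman's correlation this pair ranked 47th (0.764), and its median absolute log2 difference of 0.76 equalled the median over all pairs to 2 decimals. The array labelled K17 correlated at 0.986 with the serotype 2 strain 4226 and at 0.949 with the serotype 6 strain Femφ. The closest pair was the serotype 12 strain 1096 and the serotype 13 strain N-273 (0.995). The serotype 9 and 10 strains reached 0.971, the serotype 11 and 12 strains 0.968 and the serotype 7 and 8 strains 0.962. Of the 9 pairs above 0.9, 1 shared a serotype number and 8 were pairs on a common slide. Genes are not independent replicates, and these correlations describe single arrays. The mean correlation was 0.741 ± 0.122 (SD) over the 49 pairs on a common slide and 0.687 ± 0.0947 over the 56 pairs on different slides. Over the probes detected on all arrays, the differences of each pair were divided by their standard errors from the spots. The median absolute ratio, scaled up as for a normal spread, was at least 6.56 in every pair and includes any offset between the arrays. The error from the spots leaves out the variation between cultures and hybridizations, and the ratio does not show whether 2 arrays hold the same strain. Over the genes detected on all arrays the serotype 3 pair was again 9th (0.870) and the serotype 5 pair 64th (0.786).

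**Figure D3:**
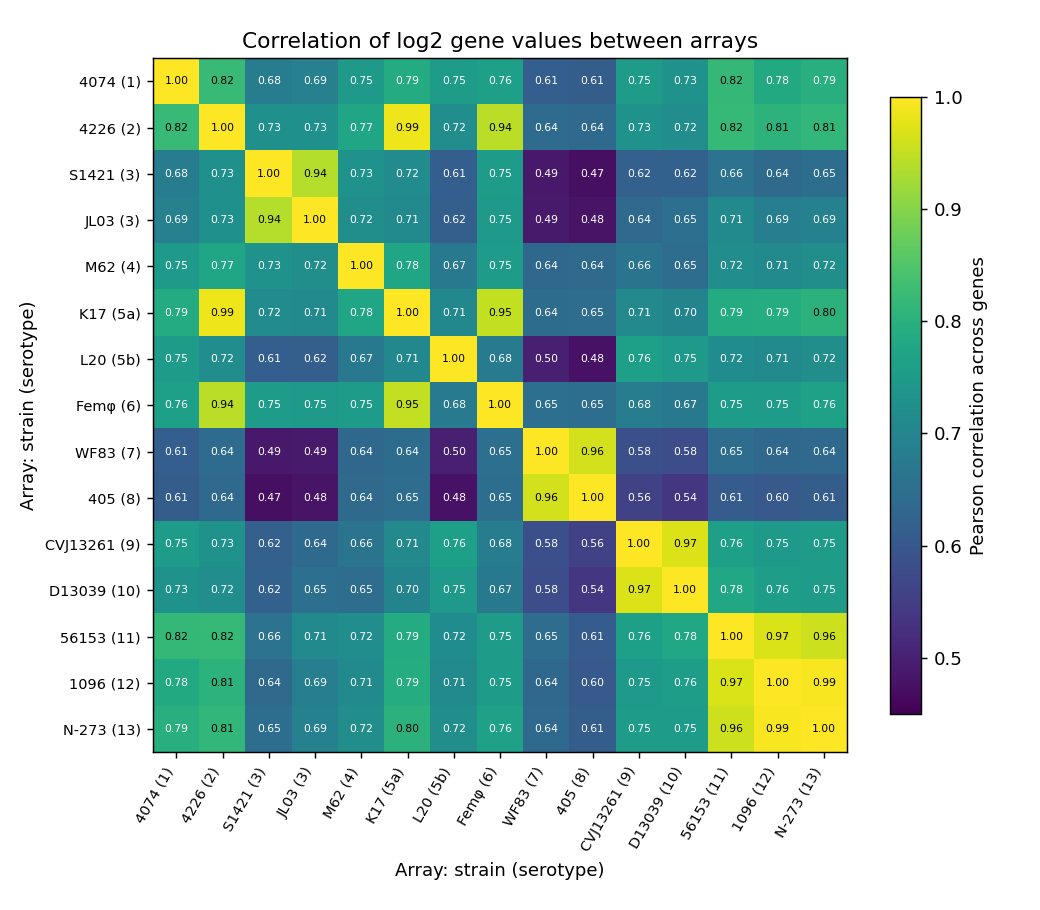
Pearson correlation across 2757 genes between each pair of the 15 arrays (both axes, strain with serotype in parentheses), shown by colour and number. The serotype 3 pair stands at 0.938 and the serotype 5a and 5b pair at 0.707, while the serotype 12 and 13 pair stands at 0.995.

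The third comparison set the 2 serotype 3 strains against the 13 strains of other serotypes. In serotype 3, 59 genes were higher and 39 lower (98 of 2757, limma with Benjamini-Hochberg adjustment). Of the higher genes, 56 carried the prefix APJL. The lower genes comprised 16 APJL, 11 NC, 6 APP_1 and 6 APP_5 genes. Among them, an APP_1 and an APP_5 identifier had mean levels of −8.50 and −8.36 in serotype 3 and −1.04 and −1.08 elsewhere. Another such pair had −11.09 and −11.03 in serotype 3 and −0.68 and −0.72 elsewhere. Each pair may stand for 1 gene, so these counts are of identifiers and may exceed the number of distinct genes. As a set, the APJL genes ranked above the other genes in serotype 3 (camera, adjusted p = 1.575e-06), also with an estimated correlation (adjusted p = 0.04706), although their median difference was 0.05 and that of the 1833 detected on all arrays −0.06. The 2087 APJL genes were ranked against the rest of the 2757, so their rank mirrors those of the other sets. The APP_1, APP_5 and NC sets, with median differences of −1.04, −1.33 and −0.65 (−0.29, −0.38 and −0.21 over genes detected on all arrays), ranked below the other genes at the preset correlation only, and with an estimated correlation their adjusted p-values were 0.05182, 0.09586 and 0.09586. Of the 48 called genes that were detected on all 15 arrays, 21 were higher and 27 lower.

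The largest increases lay in runs of consecutive APJL locus numbers. Of the 56 APJL genes called higher, 22 lay in 3 runs of at least 3 loci. A run of 14 loci around APJL_1486 was higher in serotype 3 by a median log2 difference of 11.37, with a mean level of 0.06 in serotype 3 and −11.33 elsewhere. With undetected arrays set to the lowest detected signal, the median difference of this run was 1008-fold. All 14 loci were detected on both serotype 3 arrays and on the serotype 6 array of Femφ, where their mean level was lower, at −3.65 (from −8.67 to −0.79), and at most 3 of them on any of the other 12 arrays. APJL_1486 itself was detected on 1 of the 13 other arrays, and with the 12 undetected arrays at the lowest detected signal it was 3232-fold higher in serotype 3, from a level of 1.61 ± 0.65 (SD, n = 2). The other array that detected APJL_1486 was that of Femφ, at −0.79. Without it no array outside serotype 3 detected the gene, and the fitted difference was 14.29 (adjusted p = 1.404e-13, limma). Over all arrays the fitted difference, which uses values below background, was 13.38 ± 2.30 (SE) log2 units (adjusted p = 0.002554, limma). This call was lost without S1421 (adjusted p = 0.0794, difference 12.92) and within slide 1 (adjusted p = 0.2455, difference 13.12). A run of 4 loci around APJL_1609 was higher by a median of 12.08, or 2210-fold with undetected arrays at the lowest detected signal. The serotype 3 strains differed in this run, with a mean level of −0.97 in S1421 and 2.18 in JL03. APJL_1609 was detected on 1 other array, that of L20, and was 2563-fold higher in serotype 3 with the 12 undetected arrays at the lowest detected signal. Its fitted difference was 13.19 ± 0.75 log2 units (adjusted p = 2.022e-08, limma), and it was 11.66 without JL03 and 14.72 without S1421. The SE of APJL_1609 rests mostly on the 13 other arrays (SD 0.85), 12 of them undetected, while the serotype 3 arrays had an SD of 2.16 (n = 2). With 1 term per serotype, where the spread comes from 2 pairs of arrays, its adjusted p was 0.01709 (limma, difference 13.31). With normexp background correction the fitted differences of APJL_1486 and APJL_1609 were 10.76 and 10.47. A further run of 4 loci was higher by a median of 362-fold with undetected arrays at the lowest detected signal, and all its members were detected on the serotype 4 array of M62 as well. None of the 22 loci in these runs was detected on all 15 arrays.

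**Figure D4:**
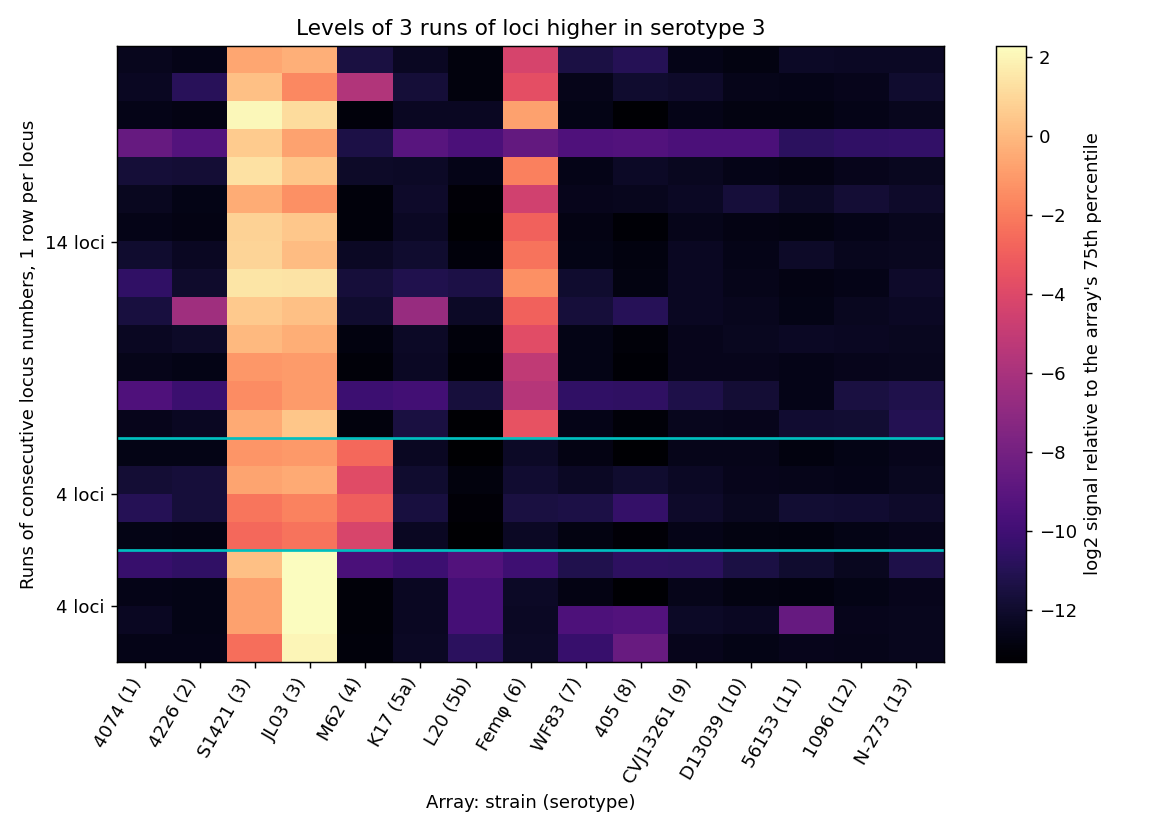
Level of each locus (rows, in 3 runs of 14, 4 and 4 consecutive APJL locus numbers separated by lines) on each array (columns, strain with serotype in parentheses), as log2 signal relative to the array's 75th percentile. The run of 14 loci is bright in the serotype 3 strains S1421 and JL03 and detected at lower and uneven levels (−8.67 to −0.79) in Femφ, the next run is also detected in M62, and the last is bright in S1421 and JL03, with all 4 loci detected but dim on L20.

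Among the lower genes, APP_5_CP000569_1418 differed by −11.49 ± 0.77 (SE) log2 units, from 0.31 ± 0.95 (SD, n = 13) in the other strains to −11.18 ± 1.84 (n = 2) in serotype 3 (adjusted p = 8.832e-08, limma). APP_1_NZ_AACK01000015_17 differed by −11.01 ± 0.67 (adjusted p = 2.999e-08, limma). Both were detected on all 13 other arrays and on 1 of the serotype 3 arrays, and with the undetected array at its lowest detected signal the differences were −10.41 and −10.38. With 1 term per serotype, their adjusted p-values were 0.009934 and 0.01739 (limma). The balance of directions depended on the scaling. Quantile normalization gave 52 higher and 74 lower genes, and scaling to the median of each array gave 51 higher and 67 lower. The median difference over all genes was −0.09 at the 75th percentile scaling and −0.32 at the median scaling, and the differences given here are not corrected for that shift. With the slide as a block 134 genes were called, and the 98 genes given above were all among them. Within either slide, most genes called were not among those 98. Each slide holds 1 serotype 3 array, which is assumed there to vary like the other strains. Without S1421 the count was 41.

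The fourth comparison set the subtypes 5a and 5b against the 13 strains of other serotypes. A single gene passed the threshold. APJL_0620 was not well above background on either serotype 5 array and was detected on all 13 others. Its bound was 791-fold lower in serotype 5 (mean −12.23 ± 0.12, SD, against −1.42 ± 1.94, with adjusted p = 0.003228, limma). This bound is no lower limit under another background correction. At an unadjusted p under 0.05 there were 95 genes. Among the genes with the smallest p-values that did not pass, APJL_1116 was 3.11-fold and NC_010939_1157 3.15-fold above the other strains, and NC_010939_2104 differed by −4.81 ± 1.11 (SE) log2 units (adjusted p = 0.6965 for each, limma). APJL_1116 and NC_010939_1157 had nearly the same mean levels, −0.50 and −0.44 in serotype 5 and −2.14 and −2.09 elsewhere. They may stand for 1 gene. The APP_5 genes as a set ranked above the other genes (camera, adjusted p = 7.808e-13) but not with an estimated correlation (adjusted p = 0.09577), and their median difference was 2.27 log2 units over 100 genes and 0.27 over the 39 detected on all arrays. The arrays of the subtypes differed widely here, since L20 detected every APP_5 probe and the array labelled K17 detected 44.6%. Without the array labelled K17, 35 genes were called, and without L20 none. The call of APJL_0620 was lost without L20 (adjusted p = 0.2157, limma), where the fitted difference was −10.73 against −10.81, and with normexp background correction (adjusted p = 0.05018, limma), where it was −8.23. With the slide as a block 1 gene was called, within slide 1 0 (limma) and within slide 2 123, each with a single serotype 5 array that is assumed to vary like the other strains.

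The fifth comparison set serotype 3 against serotype 5, with 2 arrays on each side and the other 11 strains adding to the estimate of spread. In serotype 3, 38 genes were higher and 19 lower, and every higher gene carried the prefix APJL. For 27 of the 57 genes 1 side was below background on both arrays. The 5 of these with the largest bounds, all in the run around APJL_1486, had bounds of 3025-fold to 6491-fold higher in serotype 3. These bounds are no lower limit under another background correction. Among the genes detected on at least 1 array of each serotype, APJL_1610 was higher by 11.79 ± 1.60 (SE) log2 units (adjusted p = 0.000755, limma) and APJL_1609 by 11.77 ± 0.83 (adjusted p = 1.021e-06, limma). Each was below background on 1 serotype 5 array, and with that array at its lowest detected signal the differences were 10.81 and 10.80. With the spread taken from the 4 arrays of these serotypes alone, neither passed (adjusted p = 0.05308 and 0.05258), at the same differences of 11.79 and 11.77, and within slide 1 APJL_1610 did not pass (adjusted p = 0.0761, difference 11.51). APP_5_CP000569_1418 was lower, with a difference of −12.33 ± 0.99 (adjusted p = 3.069e-06, limma) that became −11.25 with its undetected serotype 3 array at the lowest detected signal, as was NC_010939_1450, at −10.33 ± 1.52 (adjusted p = 0.0015, limma). Relative to the other genes, the APJL set ranked higher in serotype 3 and the APP_1 and APP_5 sets lower, with adjusted p-values of 0.04019, 0.04019 and 0.03567 at an estimated correlation (camera). The median differences of these sets were −0.03, −0.42 and −4.19 log2 units, and −0.11, −0.32 and −0.48 over their genes detected on all arrays. Together with NC, the sets make up all genes tested, so their ranks depend on each other. The calls contained 6 of the 100 APP_5 genes tested, an odds ratio of 3.26 (Fisher's exact test, two-sided, unadjusted p = 0.01589, 1 of 4 prefixes tested). Against the other serotypes the same test of serotype 3 gave 1.78 (Fisher's exact test, p = 0.1674). It counts correlated genes as independent. The APP_5 results here cannot be separated from the L20 array, which detected every APP_5 probe, against 44.6% on the array labelled K17. Quantile normalization gave 41 higher and 37 lower genes. The count was 72 with the slide as a block, and it fell to 29 without L20 and 33 without S1421. Within slide 1 it was 44 and within slide 2 228, where each side is 1 array that is assumed to vary like the other strains.

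The last comparison set the field strain JL03 against the serotype 3 reference strain S1421, 1 array each, with no test. At a log2 difference of at least 1, 363 genes were higher in JL03 and 329 in S1421, of 2757. The median absolute difference was 0.52 log2 units. Among the pairs of JL03 with the other 14 arrays this count of 692 was the lowest, the others lying between 962 and 1229. APJL_0007 was 512-fold higher in JL03 (9.00 ± 0.03 log2 units, SE from the spots), and APJL_0323 differed by −7.46 ± 0.04 log2 units, 176-fold higher in S1421. Both were detected on both arrays, and genes detected on 1 of them were not ranked. The dim level was −7.44 for APJL_0007, in S1421, and −5.80 for APJL_0323, in JL03. Under the alternatives, the value of APJL_0007 moved in 4 and stayed the same in 2. That of APJL_0323 moved in 3 and stayed the same in 3, and neither reversed in sign. The error from the spots leaves out this dependence on the processing. Many of the genes that differed between JL03 and S1421 stood side by side in locus number. Of the APJL genes, 139 of the 280 higher in JL03 and 104 of the 220 higher in S1421 lay in runs of at least 3. JL03 alone of the pair detected 32 probes and S1421 alone 28. Scaling to the median of each array changed the split to 279 higher in JL03 and 486 in S1421, with a median difference over all genes of −0.38 against −0.12. The strains lay on different slides, so slide and strain cannot be told apart in this comparison.

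The comparisons above used the scanner arrays. In the deposited value table, 3 of the 15 columns correlated best with the array of the sample they are labelled with, at 0.998 or more, and 12 with another sample's array. The comparisons therefore hold for the strain labels of the scanner arrays.

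**Figure D5:**
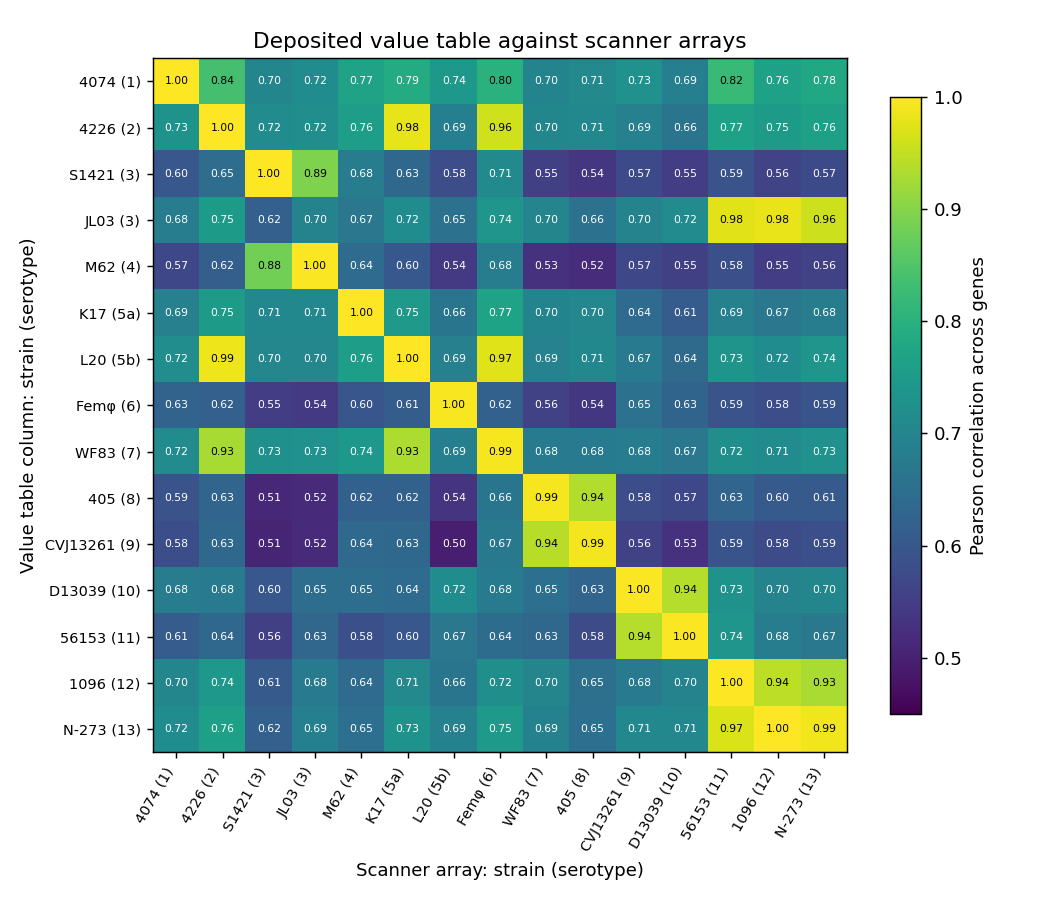
Pearson correlation across probes between each column of the deposited value table (vertical axis, strain with serotype in parentheses, as labelled) and each scanner array (horizontal axis). The columns of 4074, 4226 and S1421 correlate best with their own arrays, and 11 further columns correlate above 0.99 with the array 1 place before their own in the sample order.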

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

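The tests of the value table columns and of the serotype 5 pair were chosen only after these results had been seen. For the serotype 5 pair, a first test of the slide was kept beside a second one that was added after the first had been read. The tests of the serotype 3 genes were written before their results were seen.

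In the deposited value table, which the comparisons set aside, 12 of the 15 columns correlated best with the scanner array of another sample, and for 10 of them the correlation was above 0.99 with that array and below 0.95 with their own, which argues against the authors' normalization as the cause. For 11 columns the matching array was that of the sample 1 place before in the series order, so a column order out of step by 1 place is a candidate explanation for them. It leaves out the JL03 column, whose best match was the array of 1096 at 0.982, and the array of N-273, which no column matched above 0.99. Wrong strain labels on the JL03 and L20 scanner files are argued against, since the JL03 array detected 99.9% of APJL probes and the L20 array 100% of APP_5 probes, the most of all arrays, if the prefixes stand for the genomes of those strains, which is a hypothesis. The labels of the other arrays stay open, and no biological explanation was tested.

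The arrays labelled serotype 5a and 5b were no closer than pairs of different serotypes, at rank 59 by Pearson's and 47 by Spearman's correlation. A difference between slides is argued against as the whole cause, since a pair on different slides, that of serotype 3, reached 0.938, although that is a single pair. With each gene's slide mean removed the serotype 5 pair stood at 0.785, still below 0.9, and the serotype 3 pair at 0.889. Genes absent from a strain do not account for all of it, because the correlation was 0.786 over probes detected on all arrays, while genes whose sequence diverged from their probe can be detected at low signal and stay open. A mislabelled 5a array cannot be told apart from a real difference between the subtypes: the array labelled K17 detected 44.6% of APP_5 probes, but no array besides L20 detected nearly all of them, and a true 5a strain may lack these genes too. A difference between the subtypes that the labels name stays open and untested.

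Splits of the arrays into 2 and 13 matched or exceeded the 98 genes of serotype 3 in 2 of 100 draws. These 2 include the real split, so a random pair of arrays seldom gave as many. The splits do not settle whether serotype or another likeness of 2 arrays gave the count, because arrays that are alike are not exchangeable with others. The highest other split gave 266 genes and joined the serotype 7 and 8 strains WF83 and 405, which lie on 1 slide, and a split of the serotype 9 and 10 strains CVJ13261 and D13039, also on 1 slide and drawn only in the serotype 5 test, gave 95. The closest pairs of different serotypes gave fewer genes, 11 for 1096 and N-273 and 30 for 4226 and K17. Each of these pairs had a further close array on the other side of the split, which can lower the count. The array of 56153 correlated at 0.968 with 1096, and that of Femφ at 0.949 with the array labelled K17. Probes designed from a serotype 3 genome could raise APJL values in serotype 3 and remained undecided: among APJL probes detected on all arrays 18 of the called genes were higher and 15 lower, while the median difference over these 1833 genes was −0.06. For the rest of the APJL genes called higher, loss of the gene, a diverged sequence and lower transcription in other serotypes were not separated. For serotype 5, 18 of 100 splits gave as many genes as the single gene called, and the highest other split again gave 266, so chance could not be excluded there.

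Control spots named E1A, which the comparisons do not use, were well above background more often than the negative control spots. The share was highest on the array of strain 405, at 34.5%, and lowest on that of 56153, at 12.5%, while negative control spots reached at most 5.19%. The median share was 32.0% on slide 1 and 15.5% on slide 2.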

How the results depend on the processing

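The fits within a slide and without the arrays labelled K17 and 4074 were chosen only after the data had been seen. No paired analysis was possible because the labels give no replicate numbers that pair cultures; the fit with the slide as a block sets the serotype 3 and serotype 5 arrays of each slide against each other. The alternative of taking the brightest probe of a gene was not run, since each gene identifier had 1 probe and identifiers of the same gene could not be recognized. The gene lists and Apx toxin genes were not run for lack of gene names. Within 1.5 times the reported count of 98, serotype 3 against the other serotypes gave 102 genes with normexp, 126 with quantile normalization and 118 with median scaling. Of these, 97, 91 and 86 were among the 98. The comparison gave 40 genes on probes detected on all arrays, where fewer genes are tested, 171 with 1 term per serotype, where the spread comes from 2 pairs of arrays alone, and 1 with the deposited value table as labelled. Of the 171 genes, only 59 were among the 98. Leaving out 1 array gave 41 (without S1421) to 115 genes (without M62). Without the arrays labelled K17 and 4074 there were 95, of which 87 were among the 98. In the value table APP_5_CP000569_1418 stood at 0.18 and APP_1_NZ_AACK01000015_17 at 1.36, and for serotype 5 APJL_0620 stood at 0.23, all reversed in sign; its column labels match other arrays. Serotype 5 against the other serotypes gave 0 genes with normexp (101 at an unadjusted p under 0.05, limma), 0 with the value table (102), 0 on probes detected on all arrays (72) and 14 with 1 term per serotype. Leaving out 1 array gave 0 (without L20) to 35 (without the array labelled K17) and 2 without 4226. Within slide 1 there were 0 and within slide 2 123. Serotype 3 against serotype 5 gave 0 genes with the value table (143 unadjusted, limma), 10 on probes detected on all arrays, 115 both with 1 term per serotype and on the 4 arrays alone, which is the same estimate of spread, and 228 within slide 2. Leaving out 1 array gave 29 (without L20) to 76 (without the array labelled K17), and without both arrays labelled K17 and 4074 there were 78. The serotype 3 pair correlated at 0.645 (rank 97) in the value table and ranked 9th under the other alternatives. The JL03 column of that table matched the array of 1096 best (0.982), and the arrays of S1421 and 1096 correlated at 0.641. The serotype 5 pair, reported at rank 59, stood at 0.812 (rank 11) in the value table, at rank 47 with Spearman's correlation and at rank 81 without the filter on dim probes. The K17 and L20 columns matched the arrays labelled M62 and K17 best (0.999 each), and those arrays correlated at 0.776. By these matches, the value-table results for both pairs come from other scanner arrays than those carrying the same labels. The median count against the other strains was 465 on probes detected on all arrays and 327 at a log2 difference of 2, and the count for JL03 against S1421 was 1280 in the value table and 255 at a log2 difference of 2. Between the scanner arrays of S1421 and 1096, which the 2 value-table columns matched best, the count was 1331. Except where the text gives a reason, the cause was not tested. The size of a difference against dim or undetected arrays depends on the background correction, and the values with undetected arrays at the lowest detected signal are no lower limit under another correction. With normexp, serotype 3 against the other serotypes gave 10.76 for APJL_1486, 10.47 for APJL_1609, −9.51 for APP_5_CP000569_1418 and −9.46 for APP_1_NZ_AACK01000015_17, below the reported 11.66, 11.32, −10.41 and −10.38 at the lowest detected signal in size. Serotype 3 against serotype 5 gave 9.95 for APJL_1610, 10.01 for APJL_1609, −10.35 for APP_5_CP000569_1418 and −9.55 for NC_010939_1450, against 10.81, 10.80, −11.25 and −10.33. All 8 calls held.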

Other observations

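The tests described here were written before their results were seen. Genes with consecutive APJL locus numbers may vary together across strains. Over the 1682 such pairs detected on all arrays, the median correlation across the 15 arrays was 0.432, against at most 0.0854 in 1000 sets of random pairs. A slide effect would need the relation to vanish within slides, and the smaller of the within-slide medians was 0.450, on slide 2, against at most 0.0729 in random sets there. Shared transcription units are a hypothesis for this, but neighbouring genes that differ in sequence together between strains would give the same values, and no annotation was used to separate them.

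The serotype 9 and 10 pair, the serotype 7 and 8 pair and the trio of serotypes 11, 12 and 13 each lay on 1 slide and in adjacent positions of the sample order. The 1096 and N-273 arrays differed in detection at 16 probes, the fewest of all pairs, against a median of 216. Only 2 probes, both APJL, were detected on both serotype 3 arrays and on no other array, and 5 probes were detected on all 13 other arrays and on neither serotype 3 array.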
